A study of Homo sapiens with 38 samples.

How the data were processed

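Polyadenylated RNA of SH-SY5Y cells was sequenced in 38 libraries. One experiment held 10 groups of 3: wild-type, p53-knockout, p53;USP7 and p53;BCOR double-knockout cells in both states, and wild-type neural cells with vehicle (DMSO) or FT671. Another held wild-type and USP7-heterozygous cells in both states, 4 groups of 2. Neural cells had received 10 µM retinoic acid for 10 days per the labels' protocols, which give no dose or duration for FT671.

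Reads were aligned to hg19 with STAR and counted with HTSeq, and DESeq2 was used, per the submitters' processing notes, which name no versions. The deposited signal of a gene is its read count divided by 1 size factor per library, plus 1, as worked out from the values. After 1 was subtracted, all values of the 38 libraries were whole multiples of a step per library within 0.01 reads, which gave back the reads. Size factors ran from 0.9217 to 1.0449 and depth from 16149022 to 17946790 reads, and 1 gene took at most 2.1% of a library. The 6 columns with undifferentiated vehicle and FT671 names matched no sample and were not used. Columns of the heterozygote experiment carry other replicate numbers than the titles, so they were matched to groups only and are called first and second in the order of the columns. Of gene symbols, 352 were brought up to date by synonym and 20 that a spreadsheet had turned into dates were not named. Genes whose level is linked to the sex of a donor are not named. Results of some single genes are withheld for evaluation and not reported here.

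The design, gene lists and alternatives were set before the data were examined. It called for edgeR on counts, or limma on log2 values where a file holds normalized values, and the second applied. Genes with a mean normalized count of at least 5 over an experiment (15351 and 14820) were fitted on log2(normalized count + 1) with limma 3.58.1 (trend and robust options) in R 4.3.3. One model covered all groups of an experiment, and p-values were adjusted over genes by Benjamini-Hochberg. A gene was called at an adjusted p below 0.05. The added 1 pulls fold changes of genes with few reads towards 0, and where a group held at most 3 reads of a gene in all, levels are given without a fold change. The experiments were never fitted together. There were 22 comparisons: differentiation within each genotype, p53 loss against wild type, USP7 or BCOR loss against the p53 knockout, both losses against each other, FT671 against vehicle, vehicle against untreated cells, the heterozygote against its wild type, and 4 interactions with differentiation.

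The 27 gene lists were tested with camera in limma on the same log2 values, with a preset inter-gene correlation of 0.01, and adjusted over the lists of a comparison; lists with fewer than 3 measured members were left out. An estimated correlation was run beside it. Beside each list stand its members called over all genes and those called when adjusted over the list alone. Genes that rose or fell at least 2-fold in wild-type differentiation were tested as sets in comparisons that use none of those libraries. Shared effects are correlations, covariances and overlaps of calls. Unchanged groups against the shared controls were simulated 20 times, and the expected overlap of independent lists is the product of both call numbers over the genes tested. With 3 shared controls no split left 2 in each part, so part of the excess may come from them.

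Genes named are the targeted genes, the 6 largest changes per direction (4 for interactions and shared effects) among called genes with a mean of at least 100 and groups that did not overlap, and up to 4 members of a list with the smallest adjusted p; members of these sets were left out for length. Genes named in a comparison for which another comparison chose them (KIF1A with FT671, for example) were added after their values were seen.

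In a simulation with 200 changed genes, limma called 7 of 50 genes changed 1.25-fold, 35 at 1.5-fold, 45 at 2-fold and all 50 at 4-fold with 3 libraries a group, and 4 of 163 calls were false. With 2 a group it called 24, 40, 46 and 50, and 10 of 195 were false. Libraries of a group correlated at 0.974 or above. The spread between libraries exceeded counting error (chi-square per degree of freedom 1.6 to 101).

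Whether equal replicate numbers mark paired libraries was checked from deviations from group means. Of 135 same-numbered pairs 4 correlated over 0.1, and all 3 pairs of a comparison did so only for USP7 loss in undifferentiated cells, where the third library of each group stood apart. The replicate block gave 8811 calls there against 8798 without it. Alternatives were added values of 0.5 and 5, no filter, the replicate block, fits of only the groups compared, each library left out, edgeR 4.0.16 with TMM or RLE factors and DESeq2 1.42.0 on the recovered reads, fry, and sets at 4-fold. Added after the data were seen were TMM rescaling, edgeR with TMM as an alternative, fits without the 2 libraries that stood apart, and left-out libraries or the block for lists, sets and shared effects where not planned. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures in matplotlib 3.10.9.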

Results

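RNA was sequenced from SH-SY5Y cells, a human neuroblastoma line that grows neurites in retinoic acid, undifferentiated or after 10 days of neural differentiation. The cells were wild type, lacked p53, lacked p53 together with USP7 (a deubiquitinase) or with BCOR (a subunit of the noncanonical Polycomb complex ncPRC1.1), carried a heterozygous USP7 mutation, or received the USP7 inhibitor FT671. Each of the 38 libraries held between 16149022 and 17946790 reads in genes. Levels are mean normalized counts ± SD (n = 3 per group, n = 2 in the heterozygote experiment), and values marked log2 are fold changes ± SE from limma.

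Among genes with a mean of at least 100, wild-type differentiation raised CYP26B1 most, an enzyme that degrades retinoic acid, from 5.03±1.75 to 30014±8723 (log2 12.28±0.42). Its relative CYP26A1 rose from 0±0 to 538±202 and DHRS3, which reduces retinal, from 8.04±3.45 to 2744±546 (log2 8.29±0.20). SMOC1, a matricellular protein, rose from 2.34±0.572 to 2509.5±463 (log2 9.55±0.35), the cannabinoid receptor CNR1 from 1.34±0.576 to 912±164 (log2 8.62±0.35) and the neuroendocrine factor INSM1 from 0.334±0.579 to 463±44.5. The vascular growth factor receptor FLT1 fell from 1598±145 to 0.64±0.554 and CAVIN1, which shapes caveolae, from 939.8±14.8 to 3.19±3.36 (log2 -8.24±0.40). The secreted BMP antagonist GREM1 fell from 288±19.5 to 3.52±2.42 (log2 -6.17±0.35). The homeobox gene MSX2 fell from 371±7.37 to 3.52±1.11 (log2 -6.39±0.25) and the protease inhibitor TFPI2 from 3486±185 to 56±7.32 (log2 -5.94±0.14). Among genes of the retinoic acid list, the receptor RARB rose from 80.4±5.05 to 2310.5±210.1 (log2 4.82±0.09), the binding protein CRABP2 from 201±26.1 to 9353±1948 (log2 5.52±0.12) and the neurotrophin receptor NTRK2 from 10±2.62 to 2922±423 (log2 8.06±0.11). In all, 10091 of 15351 genes were called, 4968 up and 5123 down (50.78% up after TMM rescaling), and 1887 rose and 1367 fell by at least 2-fold. The largest adjusted p among the genes named here was 5.6e-12 (CYP26A1).

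Genes of the neuronal cytoskeleton rose as a group in wild-type differentiation: 26 of 30 rose, 1 fell and 3 were not called (26 up and 1 down adjusted over the list alone, adjusted p = 5.3e-13 for the list). MAPT (tau) rose from 136±10 to 2397±32.9 (log2 4.13±0.10) and the intermediate filament gene INA from 463±31.5 to 3912±42 (log2 3.08±0.08). The RNA-binding protein ELAVL2 rose from 56±4.24 to 1079±77 (log2 4.25±0.11). Of the synapse list 27 of 32 rose, 4 fell and 1 was not called (27 up and 4 down adjusted over the list alone, adjusted p = 1.3e-10 for the list). SNAP25, a core of the fusion machinery, rose from 441±12.9 to 2674±75 (log2 2.60±0.06). Voltage-gated ion channels gave 21 up, 6 down and 3 not called of 30 (21 and 6 adjusted over the list alone, adjusted p = 1.5e-04, but adjusted p = 0.0812 with an estimated correlation). The noradrenergic neuroblast list was mixed, with 15 up, 9 down and 5 not called of 29 (16 and 9 adjusted over the list alone, adjusted p = 0.151): the receptor kinases ALK and RET rose from 208±16.2 to 5453±238 (log2 4.70±0.08) and from 5846±275 to 46957±5434 (log2 3.00±0.09). Of the mesenchymal neuroblastoma list, 4 of 31 rose, 24 fell and 3 were not called (4 up and 24 down adjusted over the list alone, adjusted p = 1.5e-07 for the list). The matrix protein SPARC fell from 8282±239 to 1896±43.6 (log2 -2.13±0.05), the collagen COL5A1 from 6101±341 to 255±23.8 (log2 -4.58±0.10) and the Hippo effector YAP1 from 1345±94.7 to 271±7.78 (log2 -2.30±0.06). The fibroblast and endothelium list gave 4 up, 9 down and 3 not called of 16 (4 and 9 adjusted over the list alone, adjusted p = 0.0311, but adjusted p = 0.0812 with an estimated correlation). The extracellular matrix list gave 8 up, 19 down and 7 not called of 34 (8 and 20 adjusted over the list alone, adjusted p = 0.00673, but adjusted p = 0.445 with an estimated correlation) and WNT, NOTCH and TGF-beta target genes 9 up, 16 down and 3 not called of 28 (9 and 16 adjusted over the list alone, adjusted p = 0.0237, but adjusted p = 0.166 with an estimated correlation).

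Proliferation genes fell in wild-type differentiation. Of the S phase list 0 of 35 rose, 35 fell and 0 were not called (0 up and 35 down adjusted over the list alone, adjusted p = 4.5e-12 for the list). The nucleotide reductase RRM2 fell from 5049±124 to 2198±76.6 (log2 -1.20±0.06). The G2 and mitosis list gave 0 up, 24 down and 12 not called of 36 (0 and 24 adjusted over the list alone, adjusted p = 6.4e-05, but adjusted p = 0.168 with an estimated correlation). Genes of ribosome biogenesis followed, 1 up, 26 down and 1 not called of 28 (1 and 26 adjusted over the list alone, adjusted p = 3.5e-09), and MYC itself fell from 1793±61.7 to 284±46 (log2 -2.67±0.12). HOX genes moved up as a list, 18 up, 3 down and 3 not called of 24 (18 and 3 adjusted over the list alone, adjusted p = 0.00372, but adjusted p = 0.0812 with an estimated correlation), although HOXA13 fell from 83.1±2.95 to 0±0. Retinoic acid response genes gave 16 up, 6 down and 2 not called of 24 (16 and 6 adjusted over the list alone, adjusted p = 1.0e-04, but adjusted p = 0.0812 with an estimated correlation). Beta protocadherins gave 11 up, 0 down and 4 not called of 15 (11 and 0 adjusted over the list alone, adjusted p = 0.00218, but adjusted p = 0.162 with an estimated correlation) and cholesterol genes 17 up, 3 down and 4 not called of 24 (17 and 3 adjusted over the list alone, adjusted p = 0.00112, but adjusted p = 0.162 with an estimated correlation). The amino acid and endoplasmic reticulum stress list gave 4 up, 18 down and 6 not called of 28 (4 and 18 adjusted over the list alone, adjusted p = 0.00167, but adjusted p = 0.142 with an estimated correlation).

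The wild-type cells sequenced with the heterozygotes repeated this programme. CYP26B1 rose from 6.17±2.95 to 68592±2105 (log2 13.29±0.32), DHRS3 from 2.05±1.44 to 4639.5±349.8 (log2 10.65±0.37) and SMOC1 from 2.57±0.744 to 3321±73.6 (log2 9.88±0.28), while FLT1 fell from 301±63.3 to 1.46±0.686 and the vesicle protein RPH3A from 512±3.03 to 10.2±4.8 (log2 -5.58±0.68). Of the genes that rose at least 2-fold in the first experiment, 1528 were measured here, of which 1453 rose and 19 fell (median log2 1.71, adjusted p = 8.8e-51 for the set). Of 1079 that fell, 964 fell and 26 rose (median log2 -1.44, adjusted p = 1.1e-35). The 2 experiments were tested apart, and 11755 of 14820 genes were called in this one, 5884 up and 5871 down.

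USP7 and BCOR transcripts were lower but still read in the lines edited at them, in undifferentiated and in neural cells. USP7 fell from 3024±47.3 to 495±104 (log2 -2.63±0.09) and from 2912±91 to 674±32 (log2 -2.11±0.09) in the double knockout, and BCOR from 3605±320.5 to 1029.8±31.6 (log2 -1.80±0.09) and from 4255±160.5 to 776±76.2 (log2 -2.46±0.09) in its own. BCOR was also lower where USP7 was lost, by -0.63±0.09 and -0.79±0.09 on the log2 scale. In heterozygotes USP7 fell from 3172±22.5 to 1866±17.3 (log2 -0.77±0.04) and from 2948±42.9 to 1834±1.54 (log2 -0.68±0.04). The BCOR paralog BCORL1 rose from 1129±34.2 to 2134±34 (log2 0.92±0.09) with BCOR loss in undifferentiated cells. PCGF1, the Polycomb RING finger subunit that defines ncPRC1.1, fell in wild-type differentiation from 663±70.5 to 373±43.8 (log2 -0.83±0.11). The 10 ncPRC1.1 subunits were not called as a list in USP7 loss, 3 up, 3 down and 4 not called of 10 (3 and 3 adjusted over the list alone, adjusted p = 0.493) undifferentiated and 1 up, 4 down and 5 not called of 10 (1 and 4 adjusted over the list alone, adjusted p = 0.598) neural.

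Loss of p53 in undifferentiated cells raised neuronal genes. The kinesin KIF1A rose from 843±67.8 to 5151±322 (log2 2.61±0.10) and the granin SCG2 from 1385±62 to 7048±178 (log2 2.35±0.07). The heparan sulfotransferase HS3ST2 rose from 3.69±2.12 to 205±8.52 (log2 5.55±0.29) and the coagulation inhibitor TFPI from 5.7±2.52 to 212±31.5 (log2 5.06±0.29). The calcium buffer CALB1 rose from 9.72±3.25 to 243±6.84 (log2 4.56±0.28), the ubiquitin ligase TRIM67 from 16.8±5.02 to 415±40.9 (log2 4.59±0.16) and the phosphatase subunit PPP2R2C from 16.7±3.14 to 365±40.5 (log2 4.38±0.41). The transcription factor TFEC fell from 238±15.9 to 0.708±1.23, the fatty acid enzyme HSD17B12 from 724±64 to 19.6±4.3 (log2 -5.15±0.25) and the interferon-induced GTPase GBP4 from 637±9.12 to 31.1±5.04 (log2 -4.33±0.25). In all, 3409 genes were called, 1866 up and 1543 down (522 and 171 by at least 2-fold). Of the neuronal cytoskeleton list 25 of 30 rose, 1 fell and 4 were not called (25 up and 1 down adjusted over the list alone, adjusted p = 3.6e-26 for the list), of the synapse list 26 of 32 rose, 1 fell and 5 were not called (26 up and 1 down adjusted over the list alone, adjusted p = 1.9e-28 for the list) and of ion channels 21 of 30 rose, 4 fell and 5 were not called (22 up and 4 down adjusted over the list alone, adjusted p = 3.7e-11 for the list). p53 targets gave 2 up, 14 down and 31 not called of 47 (2 and 15 adjusted over the list alone, adjusted p = 0.0121). The cell cycle inhibitor CDKN1A fell from 739.6±33.4 to 327±26 (log2 -1.18±0.09) and PHLDA3, an AKT inhibitor, from 215±3.21 to 113±15.1 (log2 -0.93±0.10). Ribosome biogenesis genes gave 0 up, 13 down and 15 not called of 28 (1 and 13 adjusted over the list alone, adjusted p = 1.5e-04). The largest adjusted p among these genes was 2.7e-08 (PHLDA3). Skeletal muscle transcripts were high in the third of these knockout libraries alone, at 0.222% of its reads against at most 0.0153% in the other 29.

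In neural cells p53 loss lowered proliferation genes and raised interferon genes. NOS1, the neuronal nitric oxide synthase, rose from 304±44.4 to 6208±475 (log2 4.36±0.42) and PPP2R2C from 36.8±7.31 to 848±25.1 (log2 4.51±0.41). TFPI2 rose from 56±7.32 to 1199.8±98.1 (log2 4.40±0.14) and the homeobox gene HMX1 from 15±3.34 to 321±48.1 (log2 4.34±0.37). TFEC fell from 305±6.98 to 0.328±0.568, HSD17B12 from 631±14.7 to 38.4±0.453 (log2 -4.00±0.25) and the neutrophil surface protein CD177 from 213±48.9 to 31.9±0.399 (log2 -2.67±0.41). The interferon-induced gene IFI6 rose from 349±69.9 to 3393±130.3 (log2 3.30±0.14) and the peptide transporter TAP1 from 7.05±3.1 to 79.5±8.37 (log2 3.38±0.22). Of the interferon list 22 of 29 rose, 0 fell and 7 were not called (23 up and 0 down adjusted over the list alone, adjusted p = 1.4e-16 for the list). The stress list gave 19 up, 0 down and 9 not called of 28 (20 and 0 adjusted over the list alone, adjusted p = 1.3e-12). The serine enzyme SHMT2 rose from 385±12.2 to 1054±37.1 (log2 1.45±0.05). Immediate early genes gave 18 up, 1 down and 7 not called of 26 (18 and 2 adjusted over the list alone, adjusted p = 3.4e-07). EGR1 rose from 360.3±73.7 to 1184±27.2 (log2 1.74±0.12). The S phase list gave 0 up, 34 down and 1 not called of 35 (0 and 34 adjusted over the list alone, adjusted p = 1.4e-20). The helicase subunit MCM7 fell from 11937±335 to 7449±146 (log2 -0.68±0.06). The G2 list gave 0 up, 33 down and 3 not called of 36 (0 and 35 adjusted over the list alone, adjusted p = 4.6e-20). p53 targets gave 3 up, 19 down and 25 not called of 47 (3 and 19 adjusted over the list alone, adjusted p = 5.5e-05). CDKN1A fell from 615±54.4 to 209.5±21 (log2 -1.55±0.09). The synapse list gave 19 up, 0 down and 13 not called of 32 (22 and 0 adjusted over the list alone, adjusted p = 2.6e-08). In all, 4577 genes were called, 2732 up and 1845 down (552 and 208 by at least 2-fold), and the largest adjusted p among the genes named was 9.3e-06 (CD177).

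The effect of p53 loss differed between the states for 2777 genes by the interaction test, 1569 more positive and 1208 more negative in neural cells. The chemokine receptor ACKR3 had 0.338±0.585 and 0.708±1.23 in undifferentiated wild-type and knockout cells, and 46.8±11.3 and 634±39.8 in neural ones. TFPI2 had a log2 difference of 3.43±0.20, the CDC42 effector CDC42EP1 3.19±0.23, HS3ST2 -4.76±0.41, the synaptic organizer SLITRK3 -4.61±0.24 and CALB1 -4.20±0.40. Cytoskeleton effects were lower in neural cells, 2 higher, 23 lower and 5 not called of 30 (2 and 25 adjusted over the list alone, adjusted p = 2.1e-20). So were synapse effects, 3 higher, 18 lower and 11 not called of 32 (3 and 18 adjusted over the list alone, adjusted p = 3.4e-10). Interferon effects were higher, 18 higher, 0 lower and 11 not called of 29 (19 and 0 adjusted over the list alone, adjusted p = 1.1e-12).

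Loss of USP7 on the p53-knockout background turned down neuronal genes before differentiation. KIF1A fell from 5151±322 to 164±30.4 (log2 -4.98±0.10) and the microtubule protein DCX from 1561±8.73 to 86.5±18.6 (log2 -4.18±0.11). The vesicle priming factor UNC13A fell from 1444±39.4 to 40.7±7.88 (log2 -5.13±0.11) and the granin CHGA from 3034±247 to 149±39 (log2 -4.37±0.14). The neuronal splicing factor SRRM4 fell from 335±16.2 to 0±0 and the neuronal repressor MYT1L from 469±42.2 to 0.687±0.597. SEZ6L fell from 1559±17.4 to 1.99±0.921 (log2 -9.07±0.36) and the opioid receptor OPRM1 from 604±32.6 to 1.34±0.545 (log2 -8.03±0.32). The cartilage collagen COL2A1 rose from 2.71±2.09 to 1657±342 (log2 8.93±0.31) and the synaptic adhesion protein ELFN1 from 1.7±0.554 to 255±83 (log2 6.54±0.24). Prostaglandin D synthase PTGDS rose from 7.93±3.4 to 315±37.8 (log2 5.20±0.32), the GABA enzyme GAD1 from 31.8±2.46 to 864±45.7 (log2 4.72±0.12) and the adhesion gene ICAM5 from 32.7±9.14 to 809±223 (log2 4.58±0.23). In all, 8798 genes were called, 4434 up and 4364 down (1146 and 969 by at least 2-fold). The count was 4774 with only these groups in the fit, and 42.3% of calls were up after TMM rescaling. Of the cytoskeleton list 1 of 30 rose, 26 fell and 3 were not called (1 up and 27 down adjusted over the list alone, adjusted p = 3.5e-12 for the list) and of the synapse list 3 of 32 rose, 26 fell and 3 were not called (3 up and 26 down adjusted over the list alone, adjusted p = 2.0e-10 for the list). The noradrenergic list gave 3 up, 19 down and 7 not called of 29 (3 and 19 adjusted over the list alone, adjusted p = 2.8e-05, but adjusted p = 0.241 with an estimated correlation). ALK fell from 1223±27.8 to 145±25.7 (log2 -3.08±0.08). The mesenchymal list gave 15 up, 5 down and 11 not called of 31 (16 and 5 adjusted over the list alone, adjusted p = 0.00341, but adjusted p = 0.183 with an estimated correlation). SPARC rose from 7949.9±268 to 21399±979.9 (log2 1.43±0.05) and the hyaluronan receptor CD44 from 73.5±13.7 to 771±33.8 (log2 3.39±0.16). S phase genes gave 0 up, 32 down and 3 not called of 35 (0 and 32 adjusted over the list alone, adjusted p = 9.2e-15). G2 genes gave 14 up, 9 down and 13 not called of 36 (14 and 12 adjusted over the list alone, adjusted p = 0.683). The largest adjusted p among these genes was 7.9e-14 (PTGDS). In the third of these USP7 libraries genes under 1 kb exceeded genes over 4 kb by a log2 of 1.19. They did so by 0.48 in the third p53-knockout library, its control, against at most 0.17 in the libraries of the other 8 groups.

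In neural cells USP7 loss lowered the same neuronal lists and raised mesenchymal genes. KIF1A fell from 13524±686 to 558±35.7 (log2 -4.60±0.10), DCX from 5452±301 to 217±7.02 (log2 -4.65±0.11) and the dendritic protein MAP2 from 6041±150.2 to 1423±9.12 (log2 -2.08±0.06). NOS1 fell from 6208±475 to 0.658±0.57 and SRRM4 from 1409±73.3 to 0±0. CNR1 fell from 1055±69.7 to 0.322±0.557, the growth factor BMP7 from 3054±76.8 to 0.965±1.67 and HMX1 from 321±48.1 to 0±0. COL2A1 rose from 6.85±1.73 to 4689±344 (log2 9.24±0.31) and matrix Gla protein MGP from 135±18.7 to 41004±244 (log2 8.24±0.29). The protease inhibitor A2M rose from 1.95±0.971 to 1339±3.22 (log2 8.88±0.31), carbonic anhydrase CA12 from 4.88±1.67 to 1826±56.9 (log2 8.31±0.21) and the complement protease CFI from 32.2±8.64 to 6179±197 (log2 7.57±0.27). Of the cytoskeleton list 1 of 30 rose, 28 fell and 1 was not called (1 up and 28 down adjusted over the list alone, adjusted p = 3.8e-16 for the list) and of the synapse list 3 of 32 rose, 28 fell and 1 was not called (3 up and 28 down adjusted over the list alone, adjusted p = 2.5e-11 for the list). The mesenchymal list gave 26 up, 1 down and 4 not called of 31 (26 and 1 adjusted over the list alone, adjusted p = 2.5e-11). SPARC rose from 1517±61.7 to 18943±322 (log2 3.64±0.05), COL5A1 from 278±28.9 to 7499±275 (log2 4.75±0.10) and YAP1 from 234±7.8 to 1032±12.3 (log2 2.14±0.06). The matrix list gave 24 up, 5 down and 5 not called of 34 (24 and 5 adjusted over the list alone, adjusted p = 1.1e-07, but adjusted p = 0.132 with an estimated correlation). Fibrillin FBN1 rose from 1816±112 to 19245±199.9 (log2 3.41±0.08). In all, 9781 genes were called, 4716 up and 5065 down (1848 and 1555 by at least 2-fold), and the largest adjusted p among the genes named was 7.1e-17 (MGP).

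Sympathetic identity genes were lower in neural cells without USP7. ALK fell from 6941±331 to 433±3.52 (log2 -4.00±0.08) and dopamine beta-hydroxylase DBH, which makes noradrenaline, from 45799±2742 to 2677±237 (log2 -4.10±0.09). The sympathetic factor ISL1 fell from 6302±98 to 576±26.9 (log2 -3.45±0.07). The list gave 7 up, 20 down and 2 not called of 29 (7 and 20 adjusted over the list alone, adjusted p = 1.1e-04, but adjusted p = 0.263 with an estimated correlation). Fibroblast and endothelium genes gave 11 up, 3 down and 2 not called of 16 (12 and 3 adjusted over the list alone, adjusted p = 0.003). The growth factor receptor PDGFRA rose from 1079.7±56.4 to 5776±166 (log2 2.42±0.05). S phase genes gave 0 up, 30 down and 5 not called of 35 (0 and 30 adjusted over the list alone, adjusted p = 1.0e-08). The cell cycle factor E2F1 fell from 1358±89.3 to 390±23.6 (log2 -1.80±0.09). G2 genes gave 0 up, 32 down and 4 not called of 36 (0 and 32 adjusted over the list alone, adjusted p = 3.1e-06, but adjusted p = 0.159 with an estimated correlation) and ion channels 10 up, 19 down and 1 not called of 30 (10 and 19 adjusted over the list alone, adjusted p = 0.0126, but adjusted p = 0.263 with an estimated correlation).

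p53 targets were higher after USP7 loss although p53 was knocked out. CDKN1A rose from 327±26 to 2042±246 (log2 2.63±0.09) in undifferentiated cells, the kinase PLK2 from 1198±42.7 to 5560.3±395 (log2 2.21±0.06) and the stress sensor GADD45A from 438±15.6 to 1253±102 (log2 1.51±0.06). In neural cells the antiproliferative gene BTG2 rose from 273±12.7 to 2643±130.1 (log2 3.27±0.09), the autophagy regulator DRAM1 from 15.3±3.07 to 207±4.8 (log2 3.69±0.17) and the death receptor FAS from 10.4±1.49 to 183±7.83 (log2 4.02±0.24). The list gave 26 up, 5 down and 16 not called of 47 (26 and 6 adjusted over the list alone, adjusted p = 0.00123) in undifferentiated and 30 up, 7 down and 10 not called of 47 (30 and 7 adjusted over the list alone, adjusted p = 4.7e-04) in neural cells.

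**Figure D1:**
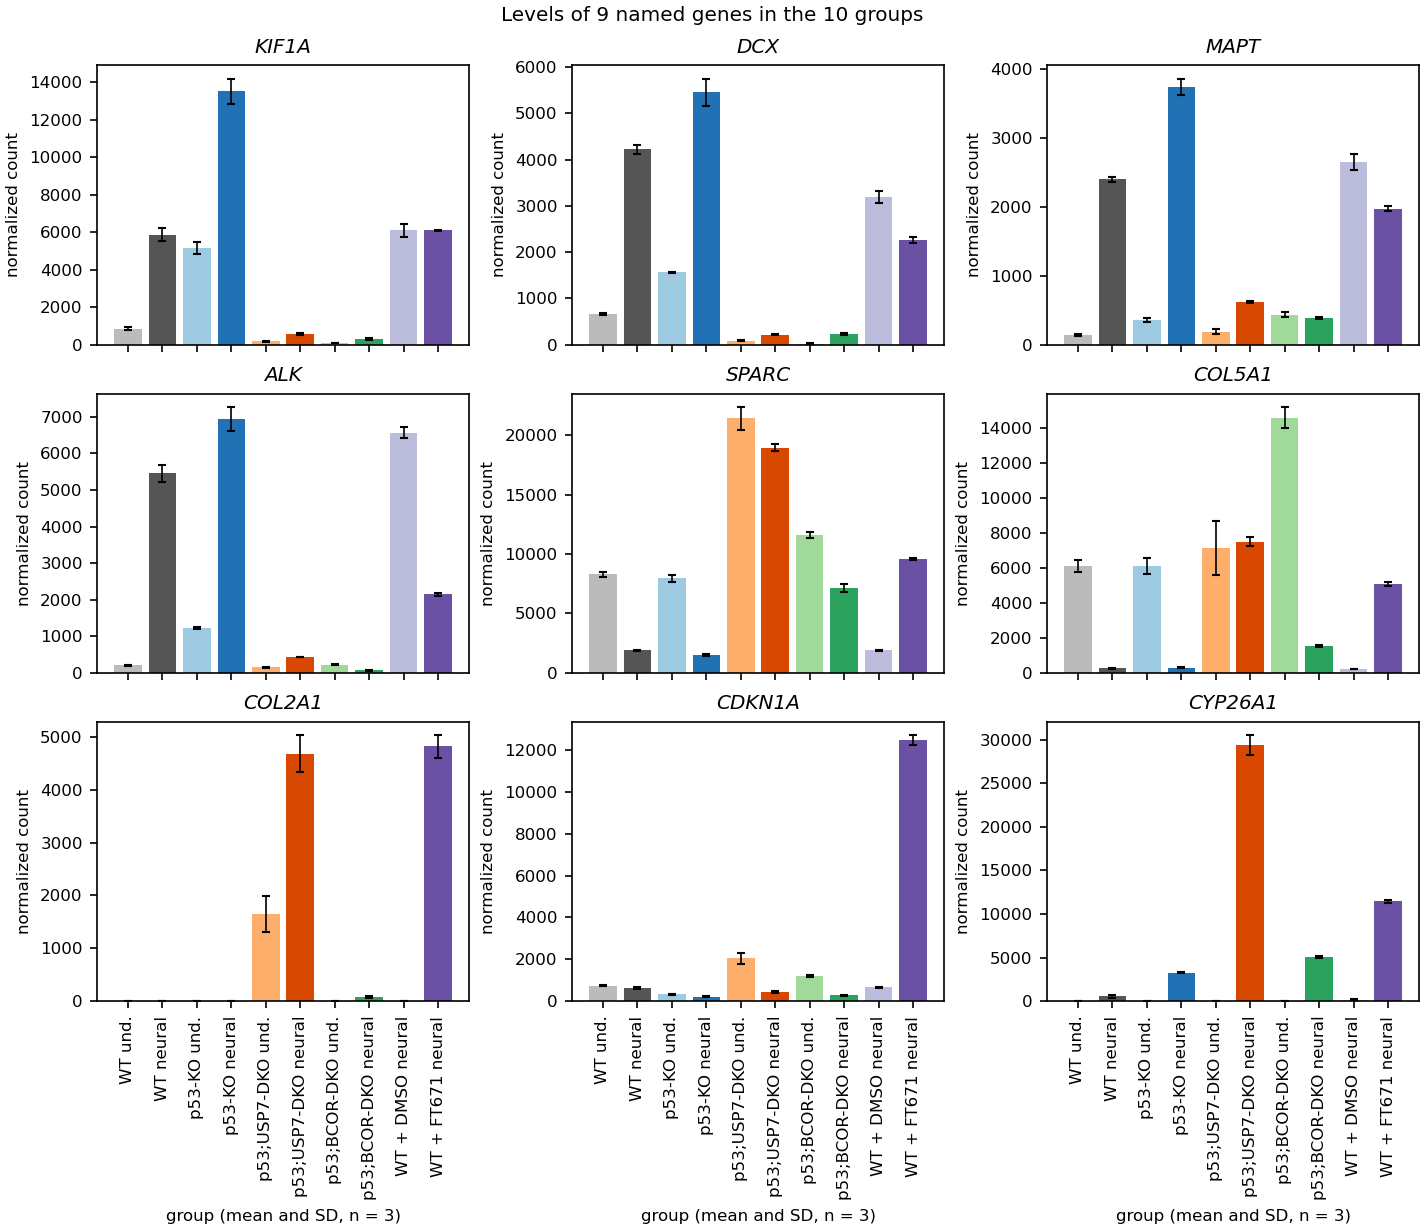
Bars show mean normalized counts of 9 genes with SD in 10 groups (n = 3 libraries each), on axes that start at 0. KIF1A stood at 13524±686 in neural p53-knockout cells and at 558±35.7 and 287±43.7 in the USP7 and BCOR double knockouts.

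Retinoic acid response genes rose as a list in differentiation of the knockout cells, with 18 up, 5 down and 1 not called of 24 (18 and 5 adjusted over the list alone, adjusted p = 3.8e-06) in p53-knockout and 19 up, 3 down and 2 not called of 24 (19 and 3 adjusted over the list alone, adjusted p = 2.8e-07) in p53;USP7 double-knockout cells. In p53;BCOR double-knockout cells the list gave 14 up, 7 down and 3 not called of 24 (14 and 7 adjusted over the list alone, adjusted p = 0.00229, but adjusted p = 0.277 with an estimated correlation). In p53;USP7 cells CYP26A1 rose from 10±7.21 to 29355±1166 (log2 11.64±0.59), the noncoding RNA H19 from 35.3±4.51 to 48469.9±7543 (log2 10.38±0.15) and the laminin LAMA4 from 21.1±4.68 to 4979.8±143 (log2 7.84±0.14), while neuropeptide NPY fell from 16796±7132 to 368±43.4 (log2 -5.43±0.18). In p53-knockout cells ELFN1 rose from 1.7±0.554 to 4701±118 (log2 10.79±0.24), NOS1 from 15.3±4.34 to 6208±475 (log2 8.61±0.42) and ACKR3 from 0.708±1.23 to 634±39.8. In p53;BCOR cells CHGA rose from 822±175 to 262579±21539 (log2 8.34±0.14) and the axonal adhesion gene CNTN2 from 0.348±0.604 to 3222±134, while the calcium sensor SCGN fell from 2269±99.7 to 0.358±0.62 and endothelin EDN1 from 443±9.92 to 1.07±0.0104. Calls numbered 10598 in p53-knockout (5462 up, 5136 down), 10060 in p53;USP7 (5205 up, 4855 down) and 8772 in p53;BCOR cells (4148 up, 4624 down). With only these groups in the fit p53;USP7 cells gave 6692, and after TMM rescaling 57.51% of calls in p53;BCOR cells were up.

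The interaction of USP7 loss with differentiation called 6466 genes, 3211 more positive and 3255 more negative in neural cells (52.92% more positive after TMM rescaling). The scavenger receptor COLEC12 had a log2 difference of 6.62±0.28, CA12 6.46±0.30, the cytokine inhibitor SOCS3 6.37±0.17, ELFN1 -9.28±0.34 and SAMD11 -6.04±0.19. Complement C4B stood at 1.36±0.566 and 0.657±1.14 in undifferentiated and 12.7±2.53 and 570.2±33.7 in neural cells without and with USP7 loss. The loss of cytoskeleton genes was larger in neural cells, 4 higher, 23 lower and 3 not called of 30 (4 and 23 adjusted over the list alone, adjusted p = 1.2e-10), as was the gain of mesenchymal genes, 23 higher, 1 lower and 7 not called of 31 (23 and 1 adjusted over the list alone, adjusted p = 2.7e-11). Ribosome biogenesis genes gave 18 higher, 0 lower and 10 not called of 28 (18 and 0 adjusted over the list alone, adjusted p = 7.5e-05) and fibroblast and endothelium genes 8 higher, 2 lower and 6 not called of 16 (8 and 2 adjusted over the list alone, adjusted p = 0.00326).

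Genes that rise in wild-type differentiation were lower in neural cells without USP7: of 1887, 354 rose and 1078 fell (median log2 -0.68, adjusted p = 2.0e-10 for the set). Of 1367 that fall in differentiation, 934 rose and 189 fell (median log2 1.00, adjusted p = 1.7e-20). In undifferentiated cells neither set was called, with 618 up and 618 down (adjusted p = 0.51) and 538 up and 357 down (adjusted p = 0.101, but adjusted p = 0.0239 without the third USP7 library and 0.0404 without this and the third p53-knockout library). Sets of genes that change at least 4-fold in differentiation were both called there, at adjusted p = 0.00332 and adjusted p = 0.00153. The interaction called both, at adjusted p = 1.8e-16 for those that rise (170 more positive, 961 more negative) and adjusted p = 1.1e-28 for those that fall (856 and 104).

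Loss of BCOR in undifferentiated cells lowered neuronal and proliferation genes. The noradrenaline transporter SLC6A2 fell from 8893±525 to 15±3.04 (log2 -9.14±0.19) and INA from 1591±77 to 35.5±6.28 (log2 -5.46±0.08). KIF1A fell from 5151±322 to 83.2±4.23 (log2 -5.93±0.10) and DBH from 10669±340.3 to 215±3.34 (log2 -5.63±0.09). RPH3A fell from 1764±78 to 1.05±1.05 and OPRM1 from 604±32.6 to 0±0. The sialomucin EMCN rose from 0.338±0.585 to 456±42.1. The transcription factor EBF3 rose from 7.24±2.97 to 1879±50.9 (log2 7.89±0.17), the DNA sensor IFI16 from 1.75±2.22 to 428±6.82 (log2 7.61±0.52) and the matrix protein POSTN from 0.354±0.613 to 205±20.7. In all, 10651 genes were called, 5472 up and 5179 down (1745 and 1720 by at least 2-fold, 48.32% up after TMM rescaling). The cytoskeleton list gave 8 up, 21 down and 1 not called of 30 (8 and 21 adjusted over the list alone, adjusted p = 1.7e-06) and the synapse list 6 up, 21 down and 5 not called of 32 (6 and 21 adjusted over the list alone, adjusted p = 1.9e-05, but adjusted p = 0.0647 with an estimated correlation). Of the S phase list 0 of 35 rose, 35 fell and 0 were not called (0 up and 35 down adjusted over the list alone, adjusted p = 1.4e-19 for the list). RRM2 fell from 8199±87.2 to 1521±88.2 (log2 -2.43±0.06). Of the G2 list 0 of 36 rose, 36 fell and 0 were not called (0 up and 36 down adjusted over the list alone, adjusted p = 3.5e-11 for the list). The kinesin KIF11 fell from 3456±80.3 to 1418±78.6 (log2 -1.29±0.05). Ribosome biogenesis genes gave 2 up, 26 down and 0 not called of 28 (2 and 26 adjusted over the list alone, adjusted p = 1.5e-06). Mesenchymal genes gave 23 up, 5 down and 3 not called of 31 (23 and 5 adjusted over the list alone, adjusted p = 2.1e-04, but adjusted p = 0.0742 with an estimated correlation). CD44 rose from 73.5±13.7 to 681±96.3 (log2 3.20±0.16). Immediate early genes gave 20 up, 2 down and 4 not called of 26 (20 and 3 adjusted over the list alone, adjusted p = 3.5e-04, but adjusted p = 0.176 with an estimated correlation). EGR1 rose from 687±30.5 to 2971±296 (log2 2.11±0.12). The largest adjusted p among these genes was 3.0e-13 (IFI16).

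In neural cells BCOR loss lowered neuronal genes and raised mesenchymal and ribosome biogenesis genes. The collagen COL3A1 rose from 7935±279 to 128048±2319 (log2 4.01±0.10) and SPARC from 1517±61.7 to 7116±314 (log2 2.23±0.05). IFI16 rose from 2.6±1.12 to 4012±184 (log2 10.16±0.52) and A2M from 1.95±0.971 to 1743±25.3 (log2 9.26±0.31). The phospholipid-binding protein ANXA1 rose from 2.28±1.13 to 1580.4±44.6 (log2 8.98±0.42) and the adaptor SASH1 from 0±0 to 429±25.5. NOS1 fell from 6208±475 to 0.71±0.615 and SRRM4 from 1409±73.3 to 1.79±3.1 (log2 -9.57±0.41). HS3ST2 fell from 1061±66.2 to 1.06±1.06 and the adhesion protein IGLON5 from 872±48.8 to 2.13±1.84 (log2 -8.39±0.33). INA fell from 3696±29.4 to 56.6±1.19 (log2 -6.01±0.08), ALK from 6941±331 to 65.5±3.25 (log2 -6.71±0.08) and the sympathetic factor TFAP2B from 4304±30.6 to 76.8±4.29 (log2 -5.79±0.06). The cytoskeleton list gave 2 up, 27 down and 1 not called of 30 (2 and 27 adjusted over the list alone, adjusted p = 1.9e-13). The synapse list gave 4 up, 26 down and 2 not called of 32 (4 and 26 adjusted over the list alone, adjusted p = 6.4e-10) and the noradrenergic list 6 up, 20 down and 3 not called of 29 (6 and 20 adjusted over the list alone, adjusted p = 3.0e-06, but adjusted p = 0.183 with an estimated correlation). The mesenchymal list gave 21 up, 6 down and 4 not called of 31 (21 and 8 adjusted over the list alone, adjusted p = 3.0e-06) and the matrix list 22 up, 7 down and 5 not called of 34 (22 and 7 adjusted over the list alone, adjusted p = 8.4e-06, but adjusted p = 0.183 with an estimated correlation). S phase genes gave 12 up, 3 down and 20 not called of 35 (10 and 3 adjusted over the list alone, adjusted p = 0.139) and G2 genes 27 up, 0 down and 9 not called of 36 (27 and 0 adjusted over the list alone, adjusted p = 8.4e-06, but adjusted p = 0.183 with an estimated correlation). Cyclin CCNA2 rose from 831±19.3 to 2033±59.9 (log2 1.29±0.08). Ribosome biogenesis genes gave 23 up, 0 down and 5 not called of 28 (23 and 0 adjusted over the list alone, adjusted p = 2.9e-05). MYC rose from 124±14.1 to 659.9±55.3 (log2 2.40±0.12). Ion channels gave 8 up, 20 down and 2 not called of 30 (8 and 21 adjusted over the list alone, adjusted p = 1.3e-04, but adjusted p = 0.114 with an estimated correlation), although the sodium channel SCN9A rose from 1106±44.5 to 6539±282 (log2 2.56±0.06). In all, 9563 genes were called, 4517 up and 5046 down (1251 and 2128 by at least 2-fold, 53.06% up after TMM rescaling), and the largest adjusted p among the genes named was 9.3e-15 (CCNA2).

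The effect of BCOR loss on proliferation genes differed between the states by the interaction test. S phase genes had 35 higher, 0 lower and 0 not called of 35 (35 and 0 adjusted over the list alone, adjusted p = 9.8e-22), G2 genes 36 higher, 0 lower and 0 not called of 36 (36 and 0 adjusted over the list alone, adjusted p = 3.4e-17) and ribosome biogenesis genes 27 higher, 0 lower and 1 not called of 28 (28 and 0 adjusted over the list alone, adjusted p = 8.2e-13). SCGN stood at 28.1±4.63 and 2269±99.7 in undifferentiated and 29±7.27 and 0.358±0.62 in neural cells without and with BCOR loss, and the chemokine CCL2 at 154±39.1, 0±0, 136±9.89 and 272±17.2. MGP had a log2 difference of 6.18±0.41, ELFN1 -7.34±0.34 and TMEM105 -6.82±0.46. In all, 9788 genes were called, 4502 more positive and 5286 more negative (52.97% more positive after TMM rescaling). Of the 1887 genes that rise in wild-type differentiation, BCOR loss raised 259 and lowered 1293 in neural cells (median log2 -1.02, adjusted p = 3.8e-19). Of the 1367 that fall, 738 rose and 336 fell (median log2 0.45, adjusted p = 9.4e-08). Neither set was called in undifferentiated cells, with 816 up and 617 down (adjusted p = 0.598) and 525 up and 550 down (adjusted p = 0.598).

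The 2 losses shared most of their calls. In neural cells 2786 genes rose in both and 3028 fell in both, against 1388 and 1665 for independent lists, and 1249 moved in opposite directions against 3041. The correlation of log2 fold changes was 0.656, where simulated unchanged groups against the same controls gave 0.501, and their covariance was 1.17 against a simulated 0.0193. In undifferentiated cells the correlation was 0.647 (simulated 0.501), the covariance 0.766 against 0.0191, and 2917 genes rose and 2764 fell in both, against 1581 and 1472. Across states the p53-knockout line is shared, but no library. Correlations were 0.461 for undifferentiated USP7 against neural BCOR loss (2013 up and 2186 down in both, against 1305 and 1434). The converse gave 0.466 (2588 and 2575, against 1681 and 1709). COL2A1 rose from 6.85±1.73 to 81.9±15.7 (log2 3.41±0.31) with BCOR loss in neural cells, and MGP rose from 135±18.7 to 18815±580.3 (log2 7.12±0.29).

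Set directly against each other in neural cells, USP7 loss and BCOR loss differed for 9351 genes, 4961 higher with USP7 loss and 4390 lower, but 43.02% of calls were higher after TMM rescaling. CHGA stood at 1736±182 with USP7 loss and 262579±21539 with BCOR loss, IFI16 at 23.9±5.25 and 4012±184, PTGDS at 2347±209 and 1.78±0.63 and the dopamine enzyme DDC at 738±37.3 and 3.92±2.24. Proliferation lists were lower with USP7 loss in neural cells, with 1 higher, 32 lower and 2 not called of 35 (1 and 33 adjusted over the list alone, adjusted p = 1.2e-13) for S phase and 0 higher, 36 lower and 0 not called of 36 (0 and 36 adjusted over the list alone, adjusted p = 1.6e-16) for G2, and higher in undifferentiated ones, with 35 higher, 0 lower and 0 not called of 35 (35 and 0 adjusted over the list alone, adjusted p = 1.2e-13) and 36 higher, 0 lower and 0 not called of 36 (36 and 0 adjusted over the list alone, adjusted p = 2.5e-15). In undifferentiated cells 10009 genes differed (6476 with only these groups in the fit), 4940 higher and 5069 lower with USP7 loss, among them SLC6A2 at 1839±368 and 15±3.04, COL2A1 at 1657±342 and 3.83±1.6 and EBF3 at 6.06±1.6 and 1879±50.9.

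The USP7 inhibitor FT671 raised p53 targets in wild-type neural cells. CDKN1A rose from 651±9.59 to 12486±234 (log2 4.26±0.09) and BTG2 from 221±6.15 to 4294±159 (log2 4.28±0.09). The death receptor TNFRSF10B rose from 629.9±33.6 to 2656±42.6 (log2 2.08±0.07) and the RNA-binding protein ZMAT3 from 756±35.3 to 2785±82.2 (log2 1.88±0.07). Of the p53 list 42 of 47 rose, 2 fell and 3 were not called (43 up and 2 down adjusted over the list alone, adjusted p = 9.4e-13 for the list). COL2A1 rose from 8.09±1.55 to 4822±215 (log2 9.06±0.31) and CA12 from 3.89±1.97 to 2162±50.8 (log2 8.87±0.21). The adhesion receptor ICAM1 rose from 14.2±3 to 4787±114 (log2 8.31±0.17), PTGDS from 2.91±0.963 to 1726±137 (log2 8.81±0.32) and ICAM5 from 7.1±3.36 to 1753±66.9 (log2 7.84±0.23). The homeobox gene DRGX fell from 2091±159 to 5.61±2.09 (log2 -8.35±0.18) and the retinol esterifying enzyme LRAT from 219±21.9 to 9.54±7.23 (log2 -4.60±0.39). Utrophin UTRN fell from 203±8.95 to 10.2±4.1 (log2 -4.25±0.21) and the LIM factor LMO4 from 219±6.06 to 13.2±4.7 (log2 -4.01±0.17). The interferon list gave 27 up, 1 down and 1 not called of 29 (27 and 1 adjusted over the list alone, adjusted p = 5.8e-09). TAP1 rose from 6.15±1.16 to 927±53.9 (log2 7.03±0.22) and HLA-C from 319.5±18 to 5550.4±135 (log2 4.12±0.08). S phase genes gave 0 up, 35 down and 0 not called of 35 (0 and 35 adjusted over the list alone, adjusted p = 3.1e-21) and G2 genes 0 up, 36 down and 0 not called of 36 (0 and 36 adjusted over the list alone, adjusted p = 1.4e-24). Topoisomerase TOP2A fell from 8033±106 to 1912±104 (log2 -2.07±0.05). In all, 9990 genes were called, 5060 up and 4930 down (2152 and 1118 by at least 2-fold, 45.1% up after TMM rescaling), and the largest adjusted p among the genes named was 4.5e-11 (LRAT).

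FT671 lowered cytoskeleton genes, 2 up, 26 down and 2 not called of 30 (2 and 26 adjusted over the list alone, adjusted p = 6.1e-08). The RNA-binding protein ELAVL4 fell from 7194±54.6 to 1741±70.3 (log2 -2.05±0.07). The inhibitor raised mesenchymal genes, 20 up, 5 down and 6 not called of 31 (20 and 5 adjusted over the list alone, adjusted p = 5.9e-05). SPARC rose from 1886±38.4 to 9557±73.1 (log2 2.34±0.05) and COL5A1 from 212±9.63 to 5068±121 (log2 4.57±0.10). KIF1A was not called (log2 0.00±0.10, adjusted p = 0.983), and the synapse list was not called, 8 up, 17 down and 7 not called of 32 (8 and 17 adjusted over the list alone, adjusted p = 0.104). The matrix list gave 23 up, 5 down and 6 not called of 34 (24 and 5 adjusted over the list alone, adjusted p = 1.2e-06, but adjusted p = 0.124 with an estimated correlation). Cholesterol genes gave 2 up, 19 down and 3 not called of 24 (2 and 19 adjusted over the list alone, adjusted p = 1.8e-04, but adjusted p = 0.115 with an estimated correlation). The Schwann cell and glia list gave 9 up, 1 down and 2 not called of 12 (9 and 1 adjusted over the list alone, adjusted p = 0.013). The neurotrophin receptor NGFR rose from 312±52.6 to 4635±301 (log2 3.90±0.17). Mitochondrial genome transcripts gave 13 up, 0 down and 0 not called of 13 (13 and 0 adjusted over the list alone, adjusted p = 4.5e-04, but adjusted p = 0.189 with an estimated correlation). MT-CO1 rose from 160890.5±9261 to 351220.3±6063 (log2 1.13±0.07). USP7 itself fell from 3038±35.7 to 2406±19.3 (log2 -0.34±0.09) and CYP26A1 rose from 174±11.1 to 11444±199 (log2 6.03±0.59). FT671 shared its changes with USP7 loss, with a correlation of 0.622 and no shared library: 3374 genes rose in both and 3237 fell in both, against 1554 and 1627 for independent lists, and 832 moved in opposite directions against 3184. With BCOR loss the correlation was 0.170 (2152 and 2022 in both, against 1489 and 1621). Of the genes that rise in differentiation, FT671 raised 623 and lowered 673 (adjusted p = 0.341, but adjusted p = 0.0478 for genes that rise at least 4-fold), and of those that fall it raised 920 and lowered 219 (median log2 0.98, adjusted p = 2.3e-16).

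**Figure D2:**
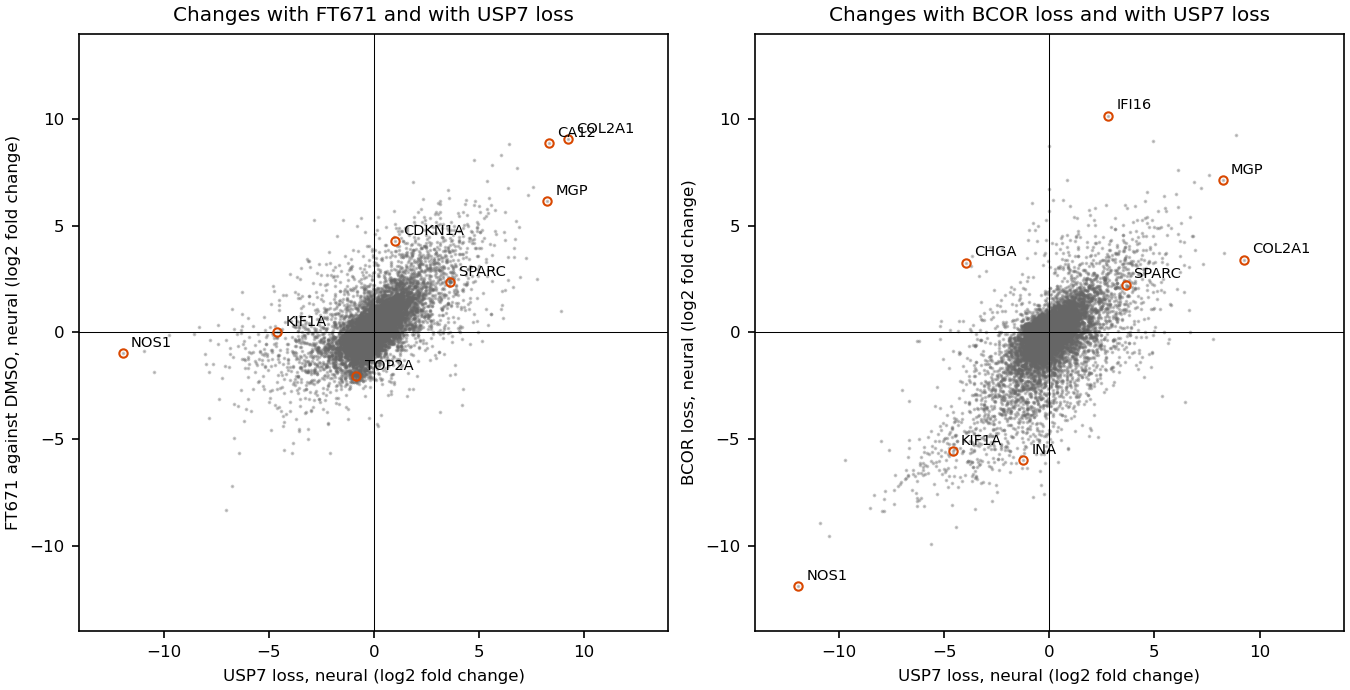
Each point is 1 of 15351 genes, with the log2 fold change of USP7 loss in neural cells on the horizontal axis and that of FT671 (left) or BCOR loss (right) on the vertical axis. The correlations were 0.622 and 0.656, the second with shared controls, and circles mark named genes.

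Vehicle alone called 1336 genes against untreated neural cells, 664 up and 672 down (96 and 57 by at least 2-fold). The count was 3725 with only these groups in the fit, 834 without the first untreated library and 802 without the third vehicle library. H19 rose from 9272±952 to 29130±6661 (log2 1.63±0.15) and the angiogenic factor VEGFA from 217±62.6 to 768±355 (log2 1.76±0.21), which was not called with only these groups in the fit. The monoamine transporter SLC18A1 rose from 42.6±7.91 to 176±100.5 (log2 1.90±0.36) and the protocadherin PCDH8 from 68.5±9.09 to 282±36.7 (log2 2.03±0.35). Tenascin TNC fell from 2384±509 to 541±70.5 (log2 -2.12±0.12), the adhesion gene CHL1 from 668±103 to 213±10.6 (log2 -1.64±0.19) and SMOC1 from 2509.5±463 to 845±92.5 (log2 -1.56±0.35). G2 genes gave 0 up, 15 down and 21 not called of 36 (0 and 24 adjusted over the list alone, adjusted p = 3.9e-14). The spindle factor TPX2 fell from 2963±44.8 to 2340.1±90.7 (log2 -0.34±0.05). Cholesterol genes gave 9 up, 0 down and 15 not called of 24 (13 and 0 adjusted over the list alone, adjusted p = 1.1e-09). INSIG1, a brake on sterol synthesis, rose from 909±119 to 1548±201 (log2 0.77±0.09). Immediate early genes gave 0 up, 8 down and 18 not called of 26 (0 and 9 adjusted over the list alone, adjusted p = 8.2e-04, but adjusted p = 0.201 with an estimated correlation).

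Cytoskeleton genes were lower in undifferentiated USP7 heterozygotes. KIF1A fell from 1742±58.4 to 352±4.62 (log2 -2.30±0.05), DCX from 1269±29.7 to 599±48.2 (log2 -1.08±0.05) and the neurofilament NEFM from 2098±32.5 to 881±76.4 (log2 -1.25±0.06). The imprinted gene NNAT fell from 1723±88 to 30.2±0.153 (log2 -5.79±0.11) and the growth cone protein BASP1 from 271±28 to 4.53±2.11 (log2 -5.67±0.20). The myosin MYO16 fell from 200.3±34.8 to 0±0, VAT1L from 243±0.514 to 2.51±2.12 (log2 -6.26±0.36) and the kainate receptor subunit GRIK5 from 351±38.7 to 15.6±3.64 (log2 -4.42±0.14). The interleukin receptor IL17RA rose from 21.6±3.05 to 199±11.8 (log2 3.16±0.18) and the LIM factor LHX8 from 104±3.61 to 574±25.6 (log2 2.46±0.14). SLITRK3 rose from 45.2±2.59 to 235±0.942 (log2 2.36±0.19) and the proteoglycan SPOCK1 from 293±0.553 to 1292±44 (log2 2.14±0.06). In all, 3768 of 14820 genes were called, 1684 up and 2084 down, with 2449 called without the first wild-type library and 2172 by DESeq2. The cytoskeleton list gave 1 up, 19 down and 10 not called of 30 (1 and 21 adjusted over the list alone, adjusted p = 1.4e-12). The synapse list gave 4 up, 16 down and 12 not called of 32 (5 and 16 adjusted over the list alone, adjusted p = 1.2e-04, but adjusted p = 0.0937 with an estimated correlation). The secreted neuropeptide precursor VGF fell from 9953±717 to 3333±165 (log2 -1.58±0.05). The G2 list gave 0 up, 34 down and 2 not called of 36 (0 and 34 adjusted over the list alone, adjusted p = 7.1e-20). The kinase PLK1 fell from 3108±188 to 1939.5±47.6 (log2 -0.68±0.06). p53 targets gave 4 up, 16 down and 26 not called of 46 (4 and 16 adjusted over the list alone, adjusted p = 0.0294, but adjusted p = 0.236 with an estimated correlation), although the p53 list was not called without the first heterozygous library (adjusted p = 0.067). The largest adjusted p among these genes was 3.1e-08 (VAT1L).

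In neural heterozygotes NNAT fell from 1340.5±64.5 to 35.3±4.79 (log2 -5.21±0.11) and BASP1 from 1262±0.826 to 70.1±10.3 (log2 -4.16±0.20). The neuronal migration protein ASTN1 fell from 258±9.01 to 13.7±3.87 (log2 -4.16±0.41) and GRIK5 from 1077±41 to 105±12 (log2 -3.35±0.14). IL17RA rose from 15.6±1.34 to 219±0.811 (log2 3.73±0.18) and H19 from 8205±316 to 38691±149.9 (log2 2.24±0.04). The nuclear receptor NR5A2 rose from 117±11.4 to 486±18.9 (log2 2.05±0.34) and the guanine exchange factor NGEF from 89.3±5.96 to 347±103 (log2 1.92±0.21). NEFM fell from 1866±136 to 744±47.8 (log2 -1.32±0.06), KIF1A from 5996±275 to 3069.7±124 (log2 -0.97±0.05) and the fusion clamp CPLX2 from 2791±21.7 to 784±51.7 (log2 -1.83±0.06). The cytoskeleton list gave 1 up, 18 down and 11 not called of 30 (2 and 19 adjusted over the list alone, adjusted p = 5.4e-12). The synapse list gave 3 up, 19 down and 10 not called of 32 (3 and 21 adjusted over the list alone, adjusted p = 2.0e-09) and G2 genes 0 up, 19 down and 17 not called of 36 (0 and 23 adjusted over the list alone, adjusted p = 3.0e-06, but adjusted p = 0.0543 with an estimated correlation). In all, 3151 genes were called, 1417 up and 1734 down (148 and 245 by at least 2-fold), with 1947 called without the first heterozygous neural library and 2029 by DESeq2. Of 1528 measured genes that rise in differentiation 157 rose and 404 fell (median log2 -0.07, adjusted p = 0.00252), but adjusted p = 0.128 with an estimated correlation. Of 1079 that fall, 245 rose and 193 fell (adjusted p = 0.0892, but adjusted p = 0.0387 without that library and 0.00359 for genes that fall at least 4-fold). In undifferentiated heterozygotes 261 and 408 of the first set (adjusted p = 0.179, but adjusted p = 1.2e-05 for genes that rise at least 4-fold) and 174 and 215 of the second (adjusted p = 0.644) rose and fell.

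Heterozygotes still differentiated, with 11329 genes called, 5663 up and 5666 down, and CYP26B1 rose from 3.53±0.73 to 54358±666 (log2 13.56±0.32). The interaction called 2400 genes, 1298 more positive and 1102 more negative (1538 in all without the first heterozygous neural library and 1199 by DESeq2). The transcriptional corepressor RUNX1T1 had a log2 difference of 2.42±0.14, the nuclear factor TOX2 2.33±0.25, the muscarinic receptor CHRM2 -2.54±0.22, SPOCK1 -2.49±0.09 and the zinc finger gene BNC2 -2.39±0.17. G2 genes fell less in neural than in undifferentiated heterozygotes, 16 higher, 1 lower and 19 not called of 36 (17 and 1 adjusted over the list alone, adjusted p = 1.8e-06, but adjusted p = 0.0958 with an estimated correlation), and cholesterol genes gave 11 higher, 1 lower and 12 not called of 24 (14 and 1 adjusted over the list alone, adjusted p = 7.7e-05, but adjusted p = 0.0958 with an estimated correlation). Neither differentiation set was called by the interaction, at adjusted p = 0.388 and adjusted p = 0.108 (for the second adjusted p = 0.0492 without that library and 0.00669 with genes that fall at least 4-fold). The heterozygote's changes correlated with those of USP7 loss at 0.267 in undifferentiated cells (751 up and 955 down in both, against 454.3 and 600.2) and 0.375 in neural cells (779 and 1069, against 410.9 and 574.3), and with those of FT671 at 0.263 (806 and 934, against 436.1 and 570.8).

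Of the other lists, axon guidance genes gave 19 up, 7 down and 9 not called of 35 (20 and 7 adjusted over the list alone, adjusted p = 0.00799, but adjusted p = 0.448 with an estimated correlation) with USP7 loss in neural cells and 14 up, 19 down and 2 not called of 35 (14 and 19 adjusted over the list alone, adjusted p = 0.89) with BCOR loss, where fry called them in the upward direction (adjusted p = 0.00374). Developmental transcription factors outside HOX gave 10 up, 23 down and 4 not called of 37 (10 and 25 adjusted over the list alone, adjusted p = 0.174) with BCOR loss and other Polycomb subunits 6 up, 15 down and 6 not called of 27 (6 and 16 adjusted over the list alone, adjusted p = 0.0401, but adjusted p = 0.179 with an estimated correlation) with FT671. With USP7 loss germline genes gave 3 up, 5 down and 2 not called of 10 (3 and 5 adjusted over the list alone, adjusted p = 0.638) and blood cell genes 1 up, 1 down and 1 not called of 3 (1 and 1 adjusted over the list alone, adjusted p = 0.893). WNT, NOTCH and TGF-beta targets gave 12 up, 13 down and 3 not called of 28 (12 and 14 adjusted over the list alone, adjusted p = 0.784), and glia genes 7 up, 2 down and 3 not called of 12 (7 and 2 adjusted over the list alone, adjusted p = 0.0848). Beta protocadherins gave 13 up, 1 down and 1 not called of 15 (13 and 1 adjusted over the list alone, adjusted p = 0.00519, but adjusted p = 0.227 with an estimated correlation) with BCOR loss in undifferentiated cells.

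**Figure D3:**
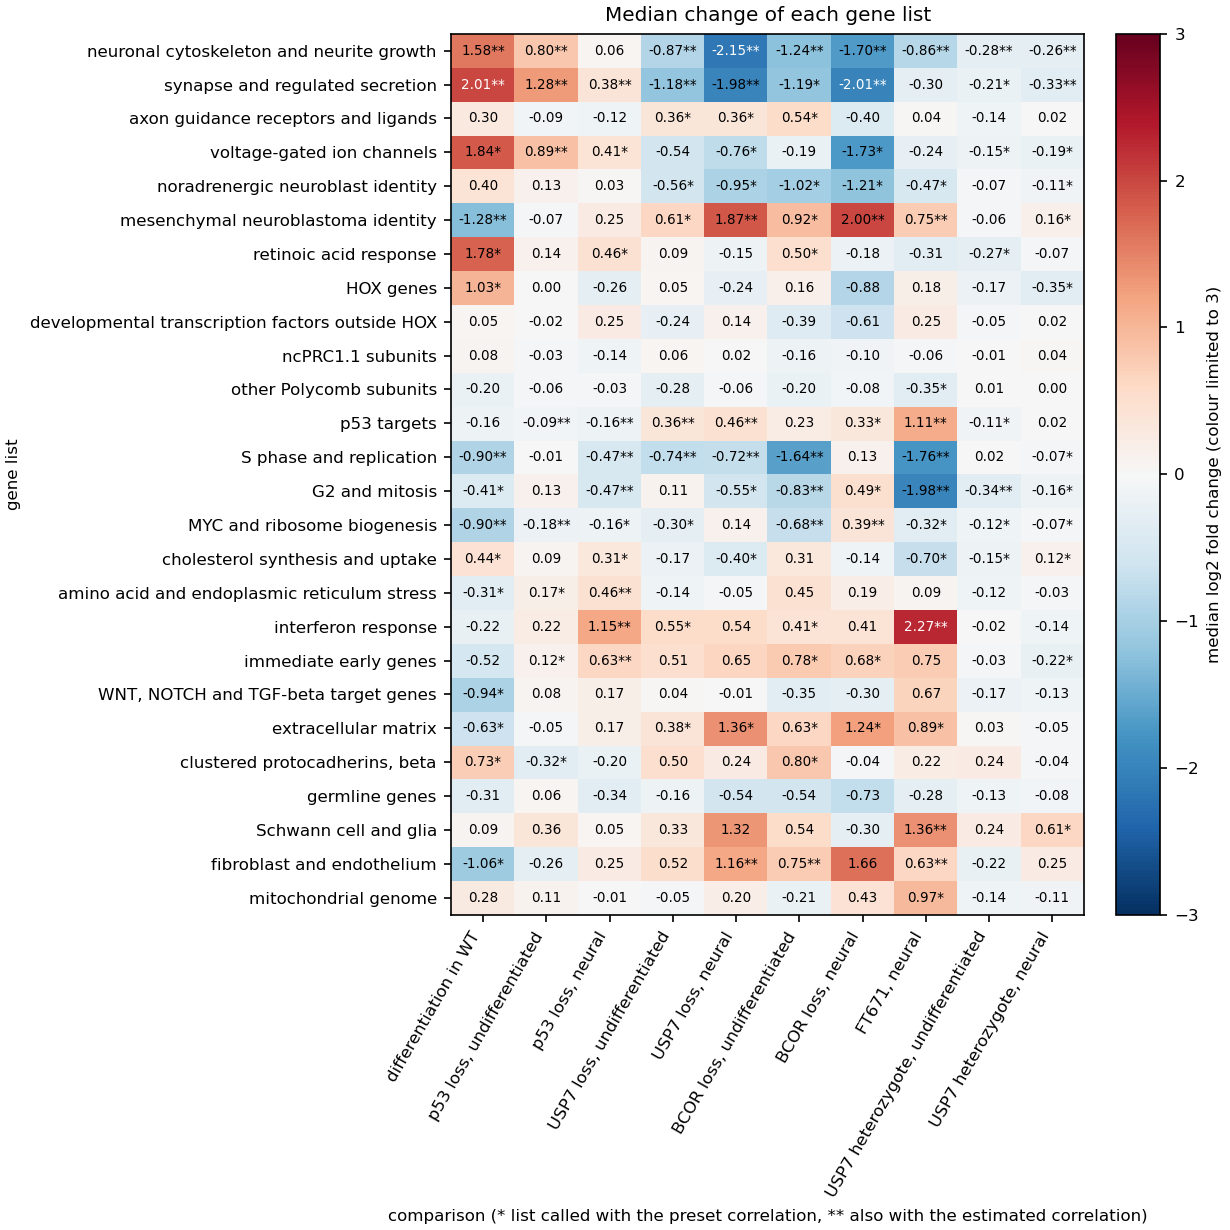
Cells give the median log2 fold change of 26 gene lists (vertical) in 10 comparisons (horizontal), with 1 asterisk for a list called with the preset correlation and 2 for one called with the estimated correlation too. The cytoskeleton list had medians of 1.58 in wild-type differentiation, -2.15 with USP7 loss and -1.70 with BCOR loss in neural cells.

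Genes with a near-identical copy, such as C4B and HLA-C, share its reads and have uncertain levels. Reads of antisense partners cannot be told apart. P-values and SE pool spread over groups (median SD 0.25 in undifferentiated USP7 double knockouts, others at most 0.102). Labels name no clones, so spread may be technical and genotype effects may be a clone's.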

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

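All tests of explanations below, and the lists of muscle genes and gene lengths behind them, were chosen only after the results were seen. The interaction tests were planned.

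The effects of genotype differed between undifferentiated and neural cells by the interaction test of limma, which singled out the values here. For USP7 loss 6466 genes were called. Log2 differences were 6.62 for COLEC12, 6.46 for CA12, 6.37 for SOCS3, -9.28 for ELFN1 and -6.04 for SAMD11, and neural double-knockout cells held C4B at 570.2, NOS1 at 0.658 and CNR1 at 0.322. Adjusted p were 1.2e-10 for cytoskeleton, 2.7e-11 for mesenchymal, 7.5e-05 for ribosome biogenesis and 0.00326 for fibroblast and endothelium genes, and 1.8e-16 and 1.1e-28 for the sets that rise and fall in differentiation. For BCOR loss 9788 genes were called, with MGP at 6.18, ELFN1 at -7.34 and TMEM105 at -6.82, and neural double-knockout cells held CNTN2 at 3222.4, CCL2 at 271.5, RPH3A at 1.07, SCGN at 0.358 and NOS1 at 0.71. Adjusted p were 9.8e-22 for S phase, 3.4e-17 for G2 and 8.2e-13 for ribosome biogenesis genes, and 7.8e-19 and 4.1e-09 for both sets.

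For p53 loss 2777 genes were called, with TFPI2 at 3.43, CDC42EP1 at 3.19, HS3ST2 at -4.76, SLITRK3 at -4.61, CALB1 at -4.20 and TRIM67 at -4.07, and neural knockout cells held ACKR3 at 634.2 and PRSS56 at 729.6. Adjusted p were 2.1e-20 for cytoskeleton, 3.4e-10 for synapse, 2.6e-17 for S phase, 5.4e-23 for G2, 7.5e-08 for stress and 1.1e-12 for interferon genes. For USP7 heterozygosity 2400 genes were called, with RUNX1T1 at 2.42, TOX2 at 2.33, VAT1L at 2.30, CHRM2 at -2.54, SPOCK1 at -2.49 and BNC2 at -2.39, and neural heterozygotes held SMOC1 at 6513 and CADM3 at 93.2.

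Skeletal muscle transcripts stood out in the third undifferentiated p53-knockout library, with CKM at 3880 against at most 5.2 in the other 29 libraries, MYH4 at 5180 against 4.3, ACTA1 at 3027.1 against 16.2 and ATP2A1 at 6359 against 174.2. Of 31 measured muscle markers 29 reached 100 there and 3 in the mean of the other 2 libraries of the group. Human muscle cells were argued against, as 8 of 22 mitochondrial pseudogenes rose above 10 times every other library while the median of mitochondrial genes deviated by 0.01. Reads from muscle RNA of another organism may be the source, since 15 pseudogenes reached 100 there and stayed under 20 in the other 29 libraries. No other explanation was tested.

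In the third undifferentiated USP7 double-knockout library 957 genes deviated over 2-fold, 936 of them upwards. The median log2 deviation of genes under 1 kb exceeded that of genes over 4 kb by 1.19, so that recovery of transcripts by length is a candidate explanation. The third undifferentiated p53-knockout library had the same shift at 0.48, and 171 of its 172 deviating genes were higher. A mislabelled library was argued against, as the USP7 library's deviation correlated at 0.1 or less with any other group's difference. No mix was simulated, so a mix stays open. No biological explanation was tested.

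p53 targets were higher after USP7 loss although p53 was knocked out. The 50 called targets above wild-type level (both states) do not exclude wild-type p53 cells here, as FT671 raised targets in such cells. Of 3 genes lost with p53, undifferentiated and neural double-knockout cells held TFEC at 0 and 0.325 (wild type 237.9 and 305.4) and MOXD1 at 0 and 1.29 (179 and 149). HSD17B12 went the other way in undifferentiated cells, from 19.6 in the p53 knockout to 156 (724 in wild type), but not in neural ones (38.4 and 40.1). The library with raised short transcripts was argued against, since the list was called without both libraries that stood apart (adjusted p = 0.00173). Return of p53 activity could not be told from other causes, because neither difference between targets that fell with p53 loss and the others passed 0.05. These had a median log2 of 0.12 against 0.41 in undifferentiated cells (permutation p = 0.0721) and of 0.41 against 0.47 in neural cells (difference of medians -0.06, permutation p = 0.751). A change of USP7 acting by another route stays open and was not tested.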

How the results depend on the processing

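Tests without the 2 libraries that stood apart, TMM rescaling, edgeR with TMM, and left-out libraries for lists, sets and shared effects were chosen only after the data were seen. Added values of 0.5 and 5, no filter, the replicate block, TMM rescaling, 3 edgeR fits and the fits without both libraries left each call count they were run on within 1.5 times and kept each call and direction of the 241 gene results named, or of the 74 that the fits without both libraries covered. Leaving out 1 library changed no call in 1460 values of these genes.

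With only the groups compared in the fit, counts were 6692 for differentiation with USP7 loss, 4774 for USP7 loss and 6476 for USP7 against BCOR loss in undifferentiated cells (10060, 8798 and 10009 with all groups), 3725 for vehicle (1336), and VEGFA lost its call with vehicle at the log2 of 1.76. DESeq2 called 2172, 2029 and 1199 genes for the heterozygote in undifferentiated cells, in neural cells and for its interaction, against 3768, 3151 and 2400. The cause was not tested. With 1 library left out vehicle gave 802 to 1011. The heterozygote gave 2449 to 2740 undifferentiated, 1947 to 2895 neural and 1538 to 2585 for the interaction. There the lone library is assumed to vary like the other groups.

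Of 589 list tests 233 were called, 96 with an estimated correlation, 448 with fry, which asks whether members change at all rather than more than other genes, and 228 to 237 with 1 library left out. That total hides changes both ways: 41 of 3864 values lost and 52 gained a call, over 57 tests, and without both libraries 6 of 243 lost and 13 gained one. Of the lists given in the text only p53 targets in undifferentiated heterozygotes lost theirs (adjusted p = 0.067). Fry turned the direction of axon guidance genes with BCOR loss in neural cells (adjusted p = 0.00374), of cytoskeleton genes in USP7 against BCOR loss in neural cells (0.0155), of ncPRC1.1 subunits in the same contrast undifferentiated (8.7e-05) and of ion channels with FT671 (7.1e-04). Of 24 set tests 14 were called, 13 with an estimated correlation, which ended the call of genes that rise in neural heterozygotes (0.128), and 20 with sets at 4-fold, which added both sets for USP7 loss in undifferentiated cells (0.00332 rise, 0.00153 fall), genes that rise for FT671 (0.0478) and undifferentiated heterozygotes (1.2e-05), and genes that fall for neural heterozygotes (0.00359) and their interaction (0.00669). Genes that fall ranged from 0.0239 to 0.292 for undifferentiated USP7 loss (0.0404 without both libraries), 0.0387 to 0.247 for neural heterozygotes and 0.0492 to 0.272 for their interaction.

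Among genes with a mean of at least 100 the correlations of USP7 and BCOR loss were 0.685 undifferentiated, 0.689 neural, 0.520 and 0.528 across states, and with FT671 0.662 for USP7 and 0.222 for BCOR loss. The correlation of USP7 loss and FT671 was 0.619 to 0.622 with 1 library left out, lowest without the second vehicle library. Shared calls over the number for independent lists rose with 2-fold calls to 5.35, 5.11, 4.64 and 3.59 for USP7 and BCOR loss in that order, 4.85 and 2.91 with FT671, and 7.84, 6.35 and 5.52 for the heterozygote with USP7 loss in both states and with FT671. After TMM rescaling the share of higher calls moved from 47.29% to 57.51% for differentiation with BCOR loss and from 53.05% to 43.02% for USP7 against BCOR loss in neural cells.

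In the larger experiment the replicate block moved no call count by over 1.5 times, gave 234 list calls and changed no other list call than that of G2 genes with p53 loss in undifferentiated cells (adjusted p = 0.0497). In the heterozygote experiment the replicate block by column number over all 8 libraries gave 2966 calls undifferentiated, 2900 neural, 11413 and 11325 for wild-type and heterozygote differentiation and 2349 for the interaction. It ended the list calls of HOX genes in neural heterozygotes (0.128) and of p53 targets in the interaction (0.0663) and added noradrenergic genes (0.0465) and WNT, NOTCH and TGF-beta targets (0.042) in wild-type differentiation.

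The 10 splits of 6 libraries cannot give a share under 0.05. Real and highest other counts were 10091 and 0 for wild-type differentiation, 10598 and 0 with p53 loss, 10060 and 1157 with USP7 loss, 8772 and 2 with BCOR loss, 3409 and 1 and 4577 and 1 for p53 loss in both states, 8798 and 3036 and 9781 and 0 for USP7 loss, 10651 and 3 and 9563 and 0 for BCOR loss, 9351 and 1 neural and 10009 and 561 undifferentiated for USP7 against BCOR loss, 9990 and 0 for FT671 and 1336 and 4 for vehicle. Of 100 splits 1, the real one, called 9788 genes for the interaction of BCOR loss (highest other 7234) and 1 called 2777 for p53 loss (2587). For USP7 loss 9 called 6466 or more, the real one and 8 (highest 8824) that kept the real groups of 1 state. Such splits carry the effect of that state by construction, and the 80 that mixed both states, which called at most 0, hold real effects in their spread. These counts therefore do not decide on chance for any of the 3 interactions.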

Other observations

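The list tests in this part were planned. Differentiation raised interferon genes in p53;USP7 double-knockout cells, 22 up, 1 down and 6 not called of 29 (22 and 1 adjusted over the list alone, adjusted p = 4.0e-06), with IFI44L, an interferon-induced gene, from 16.9±1.43 to 189.6±27.8 (log2 3.40±0.24). Mitosis genes fell in these cells, 0 up, 36 down and 0 not called of 36 (0 and 36 adjusted over the list alone, adjusted p = 8.5e-24), with the kinesin KIF23 from 2588±338 to 702±20 (log2 -1.87±0.06) and the cytokinesis factor ANLN from 5303±702 to 1361±25.9 (log2 -1.95±0.07). Fibroblast genes rose with FT671 in neural cells, 11 up, 2 down and 3 not called of 16 (11 and 2 adjusted over the list alone, adjusted p = 0.0138), with the proteoglycan DCN (decorin) from 58.2±10.1 to 489±10 (log2 3.06±0.18) and smooth muscle actin ACTA2 from 62.8±4.45 to 561±16.5 (log2 3.14±0.32). With BCOR loss in undifferentiated cells they gave 11 up, 1 down and 4 not called of 16 (11 and 1 adjusted over the list alone, adjusted p = 0.0107), with DCN from 1205±134 to 10006±177 (log2 3.06±0.18), although the endoglin gene ENG fell from 988±22.5 to 178±5.84 (log2 -2.47±0.14).

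In the heterozygote experiment wild-type differentiation raised beta protocadherins, 14 up, 0 down and 0 not called of 14 (14 and 0 adjusted over the list alone, adjusted p = 2.0e-04), with PCDHB10 from 134±8.52 to 622±29.4 (log2 2.21±0.09) and PCDHB3 from 347±3.83 to 696±31.8 (log2 1.00±0.07). Stress genes fell as heterozygotes differentiated, 5 up, 22 down and 1 not called of 28 (5 and 22 adjusted over the list alone, adjusted p = 4.8e-05), with the serine enzyme SHMT2 from 2631±176 to 283±6.13 (log2 -3.21±0.06) and PSAT1 of the same pathway from 1889±53 to 544±13.9 (log2 -1.79±0.06).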
